A study of Caenorhabditis elegans with 4 samples.

How the data were processed

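Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on Caenorhabditis elegans of the wild-type laboratory strain N2 at the L3 larval stage, grown at 20 degrees Celsius as a mixed population of males and hermaphrodites, with a rabbit polyclonal antibody (SDQ3525) against NURF-1. Of the 4 samples, 2 were NURF-1 immunoprecipitations and 2 were input DNA, numbered as replicates 1 and 2 in the labels. Per the labels' protocols, ground frozen worms were fixed first with EGS and then with EGS plus formaldehyde, the chromatin was sonicated, and libraries were made with a TruSeq kit and sequenced on Illumina instruments. Nothing in the labels says whether the replicates came from separate cultures, so the spread between them may be technical.

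The authors deposited 3 peak lists: 1 for each ChIP replicate and 1 for the series as a whole. Each row of a list gives the chromosome, start and end of a peak (1-based) and the peak's score. Per the file headers, the coordinates are on WormBase WS220, and the peaks carry the label of the peak caller MACS. The submitters' processing notes name BWA and the ce10 build. The versions, the calling threshold, the control used for each call, any filter on repeated or multiply mapping reads, and the way the ChIP replicates were combined into the series-wide list are not given in the sources used here. The scale of the deposited score is not given either. Scores were therefore used as deposited by the authors, and to rank, split or describe peaks within a list. The exception is a Pearson's r of log10 scores of shared peaks between the replicates, which uses the values themselves. Mean scores of different lists were not compared. The lists hold no read counts, so the sequencing depth is unknown, and no peak has an interval for its height. A shallower library or a weaker enrichment gives fewer peaks, and the lists cannot separate these. No values of the input samples were analysed here, so there was no comparison of ChIP with input beyond what the peak caller may have done.

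The lists were analysed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9. Chromosome lengths were taken as the last base covered by a peak in any list, since the file headers give none. Right chromosome ends therefore carry a peak by construction, and only left ends were tested. Peaks overlapped when they shared at least 1 bp. Shares of peaks were given with Wilson 95% intervals, which cover counting error only. The background for an overlap was 1000 circular shifts of the other list within each chromosome, which keep the spacing of peaks; the smallest p such a permutation allows is 0.001. Agreement of scores was computed over one-to-one overlapping peaks, across peaks, which are not independent replicates. Medians of within-list score ranks were compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. Density along chromosomes was counted in full bins of 500 kb, leaving out the last partial bin of each chromosome, and bins were compared by a two-sided permutation test with 100000 resamples. Chromosome centres were the central 50% of each chromosome and arms the outer 25% at either side, with labels permuted within chromosomes. Intervals of ratios are percentile bootstraps over bins with 1000 resamples. Neighbouring bins are not independent, so these p-values and intervals are approximate, and they describe positions within these libraries and not the spread between cultures. In what follows, higher-scored peaks have a score above the median of their list and lower-scored peaks a score at or below it.

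The statistics were tested on simulated lists and on random values. For the comparison of replicate 1 with another list, all planted overlaps were found (100% of them), and an unrelated simulated list overlapped 5.40% of the 6320 peaks against 5.07% on average over shifts. Planted peaks had been moved by less than the narrowest peak width, so finding all of them was assured. For density by chromosome, a planted X to autosome ratio of 0.556 was found as 0.566, and for centres against arms a planted ratio of 0.8 as 0.813, with 6604 simulated peaks. Of 200 bin tests without an effect, 5.5% gave a p under 0.05, and of 200 tests of medians 7%. These null tests used independent random values. Real bins are not independent and differ between chromosomes, so the null tests do not calibrate the p-values of real bins.

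Before the data were examined, the main tests, most of their alternatives and 33 gene lists were fixed. The gene lists and the tests of peaks at gene starts were not run, and base composition was not computed: the gene table at hand is for assembly WBcel235, the peaks are on WS220, no genome sequence was used, and coordinates were not carried between builds. No peak is therefore assigned to a gene. The rule fixed for this case named the 10 highest-scored series-wide peaks that overlap a peak in both replicates and the highest-scored such peak of each chromosome. The widest peaks, the chromosome ends, the runs of peaks and the densest X bin were chosen after seeing the data. Also not fixed beforehand were the tests of X against each autosome and of centres against arms by chromosome. The same holds for X against autosomes in scores, widths and centre to arm ratio, and for the test of the split by score. Alternatives covered the overlap rule, the stringency of the lists, each replicate's list alone, bin size, the extent of the centre and the counting of covered base pairs.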

Results

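Binding of NURF-1 was mapped in L3 larvae of C. elegans. NURF-1 is the worm orthologue of BPTF, the large subunit of the nucleosome remodelling factor NURF, which works with an ISWI-family ATPase to slide nucleosomes. The data are 3 peak lists, 1 for each of 2 ChIP replicates and 1 for the series. Replicate 1 held 6320 peaks, replicate 2 held 5357, and the series-wide list held 7512. Peaks were focal: the median width was 370 bp in replicate 1, 358 bp in replicate 2 and 382 bp in the series-wide list, and in each list the narrowest peak was 146 bp. Together the nuclear peaks covered 2.87% of the nuclear chromosomes in replicate 1, 2.30% in replicate 2 and 3.66% in the series-wide list. The design implies a comparison of the replicates with each other, a comparison of the series-wide list with its replicates, and a description of where in the genome NURF-1 peaks lie.

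Scores ranged widely in every list. In the series-wide list 43.8% of peaks scored under 10, 21.8% scored between 10 and 30, and 34.4% scored 30 or more. These ranges differ in width, so the shares do not show separate groups of peaks. Score and width rose together (Spearman's rho 0.77 across the 7512 series-wide peaks). Higher-scored series-wide peaks had a median width of 629 bp and lower-scored ones 228 bp.

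The first comparison asked how far the replicates found the same sites. Most peaks of each replicate were found in the other, and nearly all strong ones were. In replicate 1, 4530 of 6320 peaks overlapped a peak of replicate 2, a share of 71.7% (Wilson 95% interval 70.6 to 72.8). In replicate 2, 4648 of 5357 peaks overlapped a peak of replicate 1, a share of 86.8% (85.8 to 87.6). Circular shifts gave 5.01% on average and 17.9% at most for replicate 1, and 5.92% on average and 21.5% at most for replicate 2. The observed shares were thus 14.3 and 14.7 times the mean of the shifts, with a permutation p of 0.001 each, the smallest that 1000 shifts allow. The replicates shared 1945737 bp, which was 67.6% of the base pairs covered in replicate 1 and 84.3% of those covered in replicate 2.

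Overlap followed the score. Each list was divided into 10 classes of about equal size by score. In the lowest class of replicate 1, 27% of 630 peaks (Wilson interval 24 to 31) were found in replicate 2, and in its 3 highest classes all 636, 628 and 633 peaks were. In the lowest class of replicate 2, 52.9% of 537 peaks (48.7 to 57.1) were found in replicate 1, and in classes 7 to 10 all were. Peaks seen in 1 replicate alone were lower in rank and narrower. In replicate 1 the 1790 single peaks had a median rank at 21% of the list and the 4530 shared peaks at 64.1%, a difference of 43.1 percentage points. In replicate 2 the 709 single peaks had a median rank at 14.3% and the 4648 shared ones at 56.6%, a difference of 42.3 points. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 resamples give. Median widths were 203 bp for single and 484 bp for shared peaks in replicate 1, and 183 bp and 404 bp in replicate 2.

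**Figure D1:**
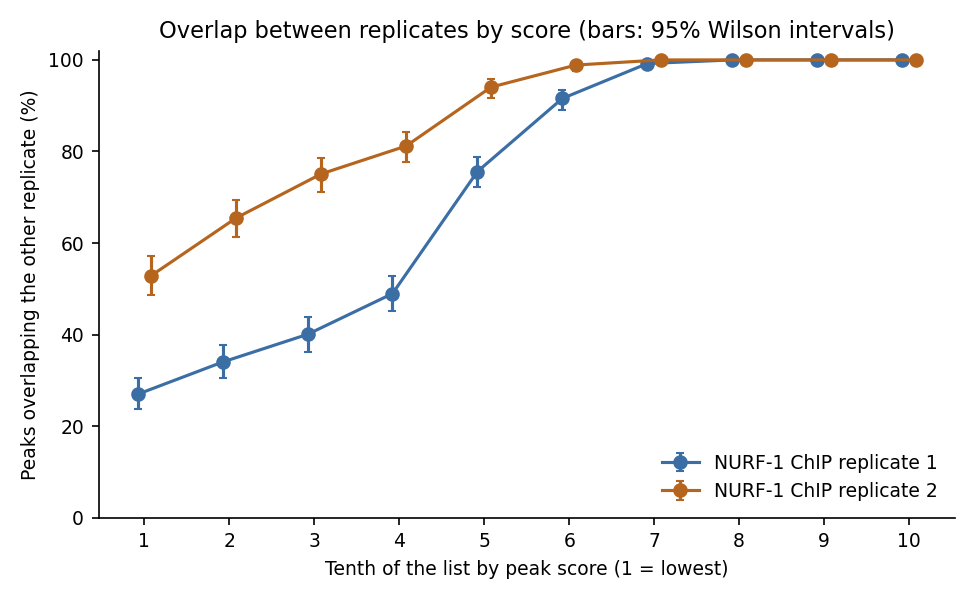
The x axis gives 10 classes of each replicate's list by peak score, from lowest to highest, and the y axis the percentage of peaks that overlap a peak of the other replicate, with points for each replicate and bars for Wilson 95% intervals. The share rises from 27% in replicate 1 and 52.9% in replicate 2 in the lowest class to 100% in the highest.

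Shared peaks were ranked alike in both replicates. Over 4135 one-to-one overlapping peaks the scores had a Spearman's rho of 0.91 (95% bootstrap interval 0.906 to 0.917) and a Pearson's r of 0.90 on the log10 scale. These correlations are across peaks, which are not independent replicates. Split by score, among 2524 pairs that were higher-scored in both lists rho was 0.87, and among 1161 pairs that were lower-scored in both it was 0.25 (0.192 to 0.302). Choosing pairs by their score in both lists narrows the range of scores, which by itself lowers rho.

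The second comparison set the series-wide list against its replicates. Of its 7512 peaks, 4346 overlapped a peak in both replicates (57.9%, 56.7 to 59.0), 1473 in replicate 1 alone (19.6%), 523 in replicate 2 alone (6.96%) and 1170 in neither (15.6%, 15 to 16). Peaks found in both had a median score of 42.2 and a median width of 596 bp. Those found in neither had a median score of 4.12, a highest score of 11.7 and a median width of 180 bp. Of the 3754 higher-scored series-wide peaks, 97.1% (96.5 to 97.6) were in both replicates and 0 were in neither (Wilson upper bound 0.102%, counting error only). Because the series-wide list combines the replicates, high support for its strong peaks may be partly built in. The series-wide list took in 96.7% of replicate 1's peaks and 97.9% of replicate 2's. The 211 and 111 peaks it lacked scored at most 9.20 and 8.27.

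Both replicates ranked the 10 highest-scored series-wide peaks near the top. This may be partly built in, since the series-wide list combines the replicates. Coordinates here are WS220. The highest-scored series-wide peak lay on chromosome I at 7020548 to 7022123 (score 257, 1576 bp wide). It ranked 5 in replicate 1 and 2 in replicate 2. The next were on chromosome II at 649926 to 650916 (score 255, ranks 2 and 1 in replicates 1 and 2), on chromosome V at 18533207 to 18534229 (score 255, ranks 1 and 4) and on chromosome III at 1618474 to 1620067 (score 252, ranks 3 and 3). They were followed by chromosome II at 9745738 to 9746656, chromosome I at 8816040 to 8817047, chromosome III at 3867318 to 3868148, chromosome IV at 14824354 to 14825767, chromosome I at 9421941 to 9422762 and chromosome II at 4047717 to 4048637. Of these 10 peaks, 3 were on I, 3 on II, 2 on III, 1 on IV, 1 on V and 0 on X. X held 785 of the 7494 nuclear series-wide peaks, so 0 of 10 does not show that strong sites avoid X. All 10 were 822 to 1594 bp wide, and each overlapped a peak among the 100 highest-scored of either replicate. The highest-scored X peak lay at 5952940 to 5953675 and was rank 16 in the series-wide list (score 209), rank 43 in replicate 1 and rank 64 in replicate 2. The highest-scored mitochondrial peak, at 13083 to 13791 of MtDNA, scored 44.5, which was rank 2103.

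The widest peaks were other sites, none of them among the 10 named above. The widest series-wide peak covered 11059 bp near the right end of chromosome I, at 15060289 to 15071347, the end that carries the array of large ribosomal RNA genes. It scored 35.6 and was 4 separate peaks in replicate 1 and 2 in replicate 2, the widest of which was 6322 bp in replicate 1 and 8225 bp in replicate 2. How multiply mapping reads were handled is not given, so NURF-1 binding at this end is not shown. The next widest were on X at 16929371 to 16935935 (6565 bp, score 62.4), on III at 2497053 to 2501810 (4758 bp, score 24.1), on X at 109526 to 114281 (4756 bp, score 21.4) and on V at 9340819 to 9345164 (4346 bp). The last of these scored 118.99, which was rank 553 in the series-wide list.

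Chromosomes differed in how many NURF-1 peaks they carried. Chromosomes III and I were the densest, with 105 and 104 series-wide peaks per Mb. Chromosome IV had 78.5, II had 75.2 and V had 55.9. The X chromosome had 44.3 peaks per Mb, the lowest of the 6 nuclear chromosomes in each of the 3 lists (36.2 in replicate 1 and 30.9 in replicate 2). The share of sequence under a peak was 5.33% on chromosome I and 1.94% on X.

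X bins held 22.2 ± 9.01 series-wide peaks per 500 kb (SD, n = 35 bins) and autosomal bins 40.6 ± 14.3 (SD, n = 162 bins). The X to autosome ratio was 0.547 (95% bootstrap interval 0.480 to 0.630, two-sided permutation p = 1e-05, the smallest the resamples allow). It was 0.530 in replicate 1's list and 0.534 in replicate 2's, with the same permutation p. These permutations exchanged bins between chromosomes, so their p does not measure how much chromosomes differ from each other. Autosomes differed too: series-wide bins held 28.0 peaks on average on V and 52.3 on III. X was below each autosome on its own: the ratio was 0.428 against I, 0.593 against II, 0.424 against III, 0.568 against IV and 0.792 against V. The Benjamini-Hochberg adjusted permutation p over these 5 comparisons was 1.25e-05 for the first 4 chromosomes and 0.00208 for V. The stronger peaks on X had lower scores than those on autosomes and were narrower. Among higher-scored series-wide peaks the median score was 41.2 for 396 X peaks and 54.4 for 3357 autosomal ones (permutation p = 0.00026), and the median width was 508 bp against 649 bp (permutation p = 1e-05). The order was the same in replicate 1 (median scores 38.3 and 53.6, permutation p = 1e-05) and in replicate 2 (27.7 and 37.9, permutation p = 8e-05). Peaks of a chromosome are not independent, so these p-values are approximate and do not measure how much chromosomes differ from each other. Among higher-scored series-wide peaks, autosomal medians ranged from 49.0 on IV to 57.2 on II. The share of higher-scored peaks did not differ detectably: it was 50.4% on X and 50.0% on autosomes, a difference of 0.409 percentage points (95% bootstrap interval -4.71 to 5.32).

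**Figure D2:**
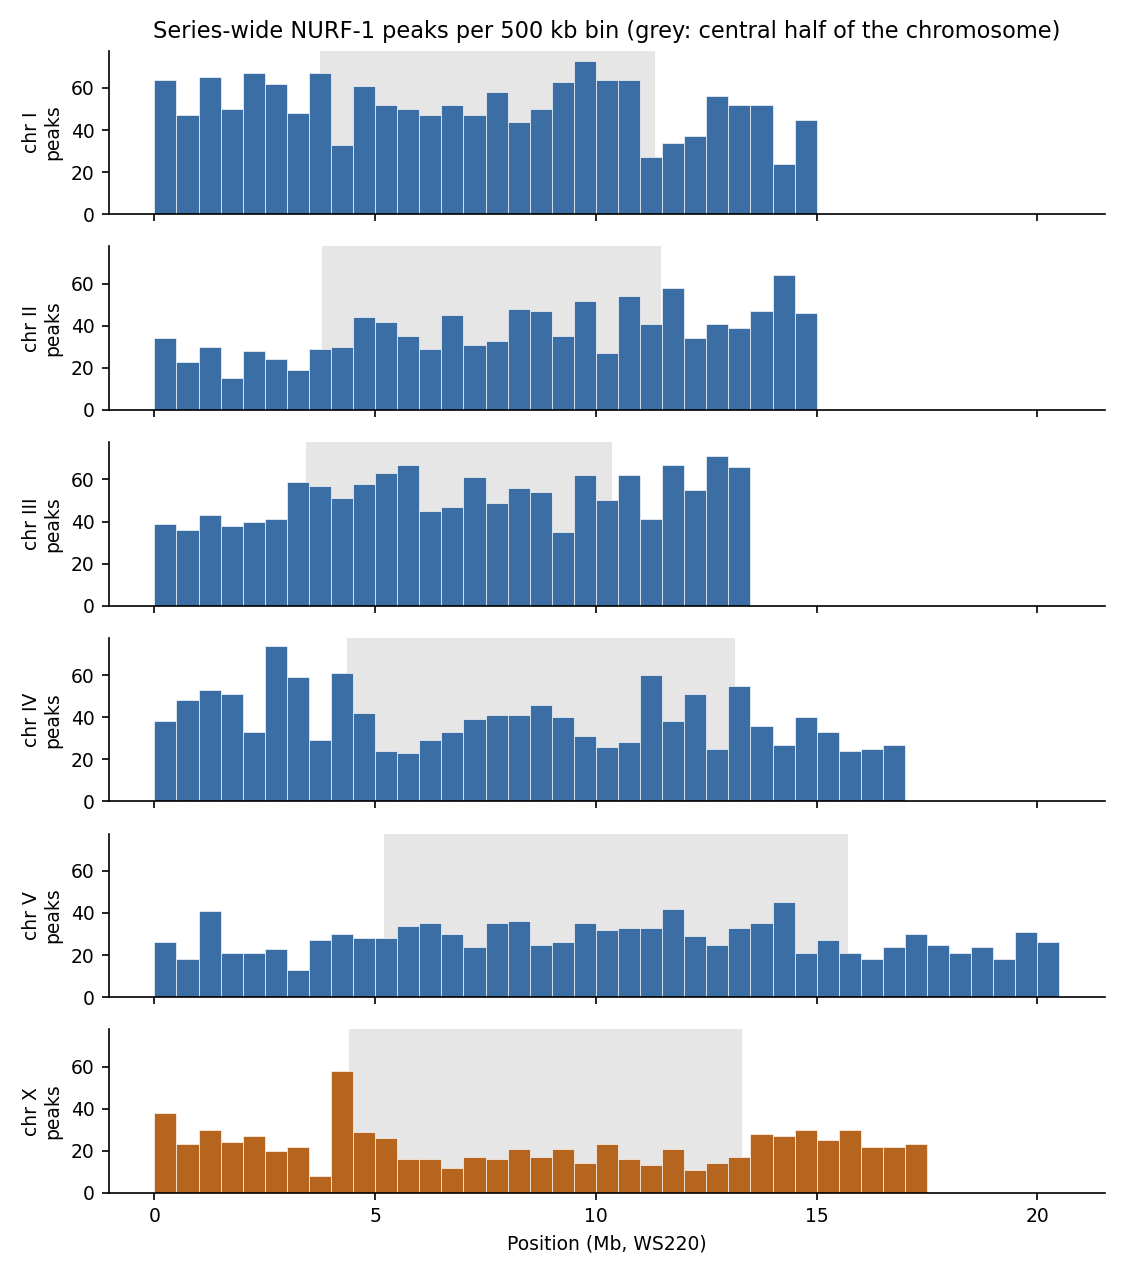
Each panel shows 1 nuclear chromosome, with position in Mb on the x axis and the number of series-wide peaks per 500 kb bin on the y axis (autosomes blue, X orange, the central 50% shaded). Most X bins lie below the autosomal mean of 40.6 peaks, and the X bin from 4 to 4.5 Mb stands out with 58.

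Within autosomes, strong NURF-1 peaks were concentrated in chromosome centres, while a difference over the whole series-wide list depended on how peaks were counted. All series-wide peaks numbered 41.6 ± 12.7 per 500 kb in centres (SD, n = 82 bins) and 39.5 ± 15.9 in arms (SD, n = 80 bins), a ratio of 1.05 (0.970 to 1.15) that did not pass the test (permutation p = 0.217). With runs of peaks under 2000 bp apart counted as 1, an alternative chosen after seeing the data, the ratio was 1.14 (1.06 to 1.23, permutation p = 0.00036). Higher-scored peaks numbered 23.5 ± 8.32 in centres and 17.1 ± 7.26 in arms, a ratio of 1.38 (1.27 to 1.50, permutation p = 1e-05). Peaks found in both replicates gave a ratio of 1.3 (1.2 to 1.42, permutation p = 1e-05). Lower-scored peaks numbered 18.1 ± 6.97 in centres and 22.4 ± 9.80 in arms, a ratio of 0.809 (0.721 to 0.901, permutation p = 0.00037). The split by score was tested itself: the excess of higher- over lower-scored peaks per bin was 10.7 peaks larger in centres than in arms in the series-wide list, 9.03 larger in replicate 1 and 6.17 larger in replicate 2, each with a permutation p of 1e-05. Lower-scored peaks alone were denser in arms in replicate 1 (ratio 0.856, 0.773 to 0.946) and not detectably so in replicate 2 (1.03, 0.919 to 1.16), and the difference between the replicates was not tested. Each replicate's full list was denser in centres, with a ratio of 1.11 in replicate 1 (permutation p = 0.00859) and 1.28 in replicate 2 (permutation p = 1e-05).

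By chromosome, higher-scored peaks favoured the centre on I (ratio 1.33), II (1.45), III (1.41) and V (1.66), with Benjamini-Hochberg adjusted permutation p-values over 6 chromosomes of 0.00389, 0.00358, 0.00117 and 6e-05. Chromosome IV did not pass (1.15, 0.886 to 1.49, adjusted permutation p = 0.349). Lower-scored peaks passed the test among autosomes on IV alone, where they were denser in arms (ratio 0.656, adjusted permutation p = 0.0101). The ratio of lower-scored peaks was 0.769 on I, 0.855 on II, 0.796 on III and 1.05 on V (adjusted permutation p = 0.0800, 0.475, 0.0800 and 0.598). No autosome passed in both score classes. Over all series-wide peaks, V was denser in its centre (ratio 1.3, 1.13 to 1.49, adjusted permutation p = 0.0012), while I (1.02), II (1.12), III (1.07) and IV (0.865) did not pass. The X chromosome passed in the other direction, with 17.8 ± 4.83 peaks per bin in its centre (SD, n = 18 bins) and 26.9 ± 10.1 in its arms (SD, n = 17 bins), a ratio of 0.661 (0.527 to 0.813, adjusted permutation p = 0.0012). Its higher-scored peaks had a ratio of 0.777 (adjusted permutation p = 0.0611) and its lower-scored peaks 0.560 (adjusted permutation p = 0.00312). The log2 centre to arm ratio of higher-scored peaks was lower on X than on autosomes by a difference of -0.83 (95% bootstrap interval -1.21 to -0.44).

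**Figure D3:**
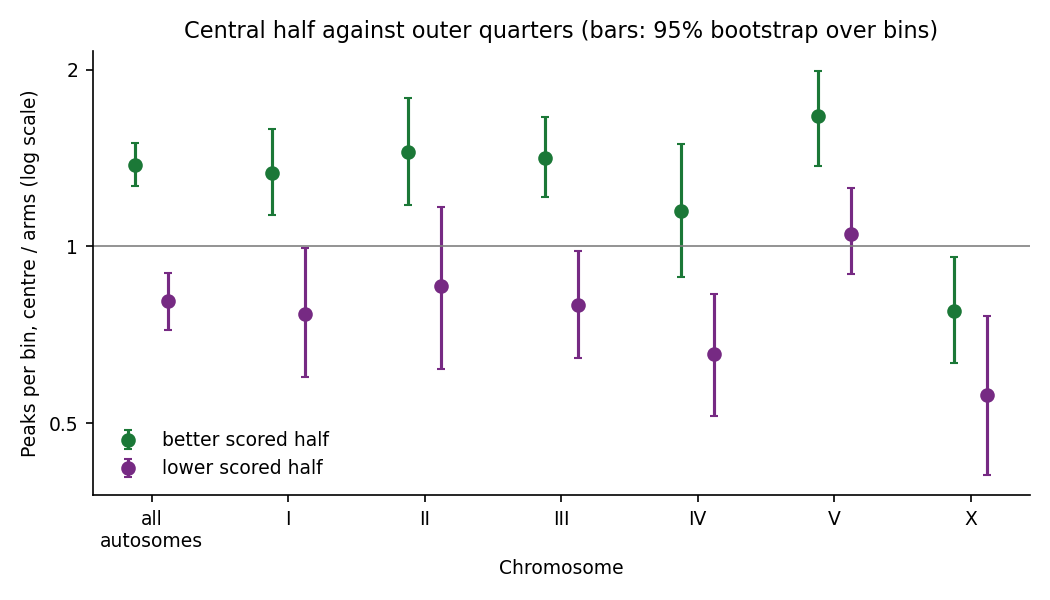
The y axis (log scale) gives the number of series-wide peaks per 500 kb bin in chromosome centres divided by that in arms, for all autosomes and for each chromosome on the x axis, with higher-scored peaks in green, lower-scored peaks in purple and bars for 95% bootstrap intervals over bins. Over all autosomes the ratio is 1.38 for higher-scored and 0.809 for lower-scored peaks, and on X both lie below 1.

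Every nuclear chromosome end carried a peak. In each of the 3 lists a peak began at base 1 of all 6 nuclear chromosomes. Circular shifts of the series-wide list put a peak within 500 bp of 0.223 of these 6 left ends on average and of 2 at most (permutation p = 0.001, the smallest 1000 shifts allow; a test chosen after seeing the data). On the right, the last peak of each of the 6 chromosomes ended at the same base in all 3 lists. That base was itself taken as the chromosome's length, so the right ends were not tested. The 12 series-wide peaks at both kinds of end were 212 to 646 bp wide and scored 13.3 to 47.8. Their median rank was at 58.8% of the series-wide list, at 53.4% in replicate 1 and at 66.4% in replicate 2. Worm chromosome ends carry telomeric repeats. Any filter on multiply mapping reads is not given and no input values were analysed, so these peaks are not shown to be NURF-1 binding at the ends.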

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

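The test in this part was chosen after the result was seen.

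The series-wide list held 18 peaks on mitochondrial DNA, which lie outside the nuclear comparisons. They were singled out because they exceed the 3 counts that a count of 0 allows, in sequence left out of the density comparisons. The overlap, support and score comparisons did count them, so the 1170 series-wide peaks in neither replicate include 15 mitochondrial ones. They covered 58.2% of the mitochondrial sequence, against 3.66% for the nuclear chromosomes. Replicate 1 had 1 mitochondrial peak and replicate 2 had 3, and 15 of the 18 were in neither. The peak at 13083 to 13791, with a score of 44.5, was in both. An even gain of weak peaks in the series-wide list was tested against nuclear peaks of the same scores (3.81 to 11.3). Of 17 weaker mitochondrial peaks, 15 (88.2%, Wilson 65.7 to 96.7) were absent from both replicates, against 654 of 2743 nuclear peaks (23.8%, 22.3 to 25.5). Fisher's exact p was 4.26e-08, which argues against an even gain. The 17 peaks are neighbours on the same molecule and not independent, so this p and the interval overstate the certainty. The control behind the series-wide call, and a different mitochondrial share in the ChIP and input libraries, may account for the gain; neither was tested, and the labels give no group that would test a biological explanation.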

How the results depend on the processing

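The splits into lower- and higher-scored pairs, the lower-scored peaks, the merged runs and the omission of the densest X bin were added after seeing the data. Of 41 alternatives, 30 left direction, test outcome or value as reported, by criteria that differed between results. The 8 overlap alternatives of each replicate passed the test against background and counted as unchanged. Among them, replicate 1's share fell from 71.7% to 58.3% when at least 200 bp had to overlap. The share of series-wide peaks in both replicates had no such test, and its fall from 57.9% to 50.4% counted as a change. The tally therefore does not measure how stable the values were. The replicate overlap stayed above its background under all 8 alternatives for each list, at 58.3% to 88.7% for replicate 1 and 69.8% to 95.7% for replicate 2. The X to autosome ratio stayed between 0.486 (base pairs covered) and 0.635 (runs of peaks with gaps under 2000 bp counted as 1). The share of series-wide peaks in both replicates was 50.4% when 50% of the peak had to be overlapped and 97.1% among higher-scored peaks. The Spearman correlation of scores between replicates was 0.80 with widths in place of scores, 0.87 for higher-scored and 0.25 for lower-scored pairs. The centre to arm ratio of 1.05 depends on which peaks are counted: it passed the test with either replicate's list alone (1.11 to 1.28), with peaks in both replicates (1.3), with higher-scored peaks (1.38) and with runs counted as 1 (1.14, permutation p = 0.00036), and it reversed to 0.81 with lower-scored peaks. These alternatives count other sets of peaks by construction. For the arm excess of lower-scored peaks, split-off flanks of strong sites and unreplicated calls are weighed at the end. Other causes were not tested. No paired analysis was possible because no values of the input samples were analysed. The alternatives set beforehand for gene starts and gene lists were not run. With 2 replicates and no read counts, depth and enrichment cannot be separated, and a peak missing from 1 list is not shown to be unbound.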

Other observations

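Chosen after seeing the results were the runs and the dense X stretch, the test of detection sensitivity on X, and the tests on lower-scored peaks, while the X ratio of peaks in both replicates was an alternative set beforehand, used to weigh an explanation only afterwards.

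NURF-1 peaks came in runs. Neighbouring series-wide peaks were under 2000 bp apart in 32.5% of cases, against 15.5% on average and 16.7% at most in 1000 random placements that kept the number per 500 kb. Joining such neighbours gave 5064 runs, of which 3667 were single peaks and 13 held 10 or more. Several long runs formed broad stretches. On chromosome II, 17 peaks lay between 9808046 and 9824649, covered 76.6% of that stretch and scored 11.7 at most. Replicate 1 had 19 peaks there and replicate 2 had 16, but only 8 of the 17 overlapped a peak in both. On chromosome I, 15 peaks between 10204121 and 10219213 covered 82.1% of the stretch. They had a median score of 13.4, above the series-wide median, and a highest score of 15.2. Replicates 1 and 2 had 14 and 15 peaks there, and 10 of the 15 series-wide peaks overlapped a peak in both. Another 17 peaks on II between 14598720 and 14608472 had a median score of 3.39, with 6 peaks in each replicate. Of these 17, 1 overlapped a peak in both replicates and 5 in neither. Other long runs held a strong peak: 11 peaks on II from 10541686 to 10552441 reached a score of 64.7, and 10 peaks on IV from 2703807 to 2713915 reached 71.05. Of these, 5 of the 11 and 3 of the 10 overlapped a peak in both replicates. The densest 500 kb bins were on IV from 2.5 to 3 Mb (74 peaks), on I from 9.5 to 10 Mb (73) and on III from 12.5 to 13 Mb (71).

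The X chromosome had 1 bin far above its others. From 4 to 4.5 Mb it held 58 peaks, against 21.1 ± 6.61 in the other 34 X bins (SD) and 38 in the next highest. Of these, 31 lay in a stretch of 30.4 kb at 4026023 to 4056401, with a median score of 5.09 and a highest score of 20.9. Each replicate had 12 peaks in the stretch, and 16 of the 31 were in neither. Without the bin, X bins had a centre to arm ratio of 0.713 (permutation p = 0.0009). The longest stretch without a series-wide peak was 299 kb on V, from 19221262 to 19520081, and held 1 peak of replicate 1 and 0 of replicate 2.

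Fewer peaks on X could come from lower detection sensitivity there, which would shift scores down and lose weak peaks. The share of higher-scored peaks on X differed from that on autosomes by 0.409 percentage points (95% bootstrap interval -4.71 to 5.32), but a list truncated at a threshold can keep that share when scores shift down, and strong X peaks did score lower (median 41.2 against 54.4), so lower sensitivity and fewer sites cannot be told apart. The low X density did not rest on unreplicated peaks, since peaks in both replicates gave a ratio of 0.540 (0.465 to 0.618). Open and untested are fewer gene starts per Mb on X, the single X of males in a mixed population, and a difference in NURF-1 binding. A single X would itself lower sensitivity, but the share of males is not given, so the size of that effect is unknown.

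Over all autosomes, weak peaks were denser in arms and strong peaks in centres, although no single autosome passed both tests. Split-off flanks of strong sites may be among the weak peaks, of which 19.7% lay within 1000 bp of a strong one (shifts gave 11.4% on average), but the 2653 autosomal weak peaks farther away still had a centre to arm ratio of 0.794 (0.704 to 0.895), which argues against flanks as the whole cause of the arm excess; the 699 nearer ones had 0.868 (0.733 to 1.02). If the arm excess of weak peaks came from calls of 1 library or of the series-wide list alone, fewer arm peaks should recur: 18.3% of lower-scored arm peaks and 19.8% of centre peaks were in both replicates, a difference of -1.49 points (95% bootstrap interval -3.97 to 0.893). The interval reaches -3.97 points, and recurrence was low everywhere. A somewhat smaller share of recurring peaks in arms is therefore not excluded, and the comparison cannot decide. Replicate 2's weak peaks had no detectable arm excess (1.03, 0.919 to 1.16). The 635 weak autosomal peaks in both replicates gave a ratio of 0.897 (0.762 to 1.06). An origin in calls of replicate 1 or of the series-wide list alone thus cannot be told apart from an arm excess of weak sites. The concentration of strong peaks in centres was in both replicates, at 1.46 in replicate 1 and 1.59 in replicate 2, and why it differs on X was not tested.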
